A study of Caenorhabditis elegans with 2 samples.

How the data were processed

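The data are chromatin immunoprecipitation followed by sequencing (ChIP-seq) of the nuclear hormone receptor NHR-28 in the nematode Caenorhabditis elegans. Per the labels, the worms were embryos of mixed stages and both sexes of strain OP317, which carries the unc-119 allele ed3 and an integrated transgene, wgIs317, that tags nhr-28 with eGFP. The 2 libraries are labelled as biological replicates 1 and 2 and come from whole organisms, with fragments of 150 to 350 bp. Both belong to 1 group, and no untreated, untagged or other-stage group was analysed here, so each comparison sets replicates, lists of regions or classes of genome features against each other.

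Per the libraries' text records, the authors called regions against a control on each replicate and on both replicates together, with a relaxed setting that keeps peaks and background as input for the irreproducible discovery rate (IDR) step, and deposited the list that passed IDR. The aligner, the peak caller, the IDR version and its cutoff are not given in the sources used here, and nor are read totals, so the sequencing depth of each library is unknown. The deposited lists give each region's signal value, the authors' measure of its strength against the control, whose scale depends on the library, so that levels were compared within 1 list only, and between the replicate lists only by correlation. In the replicate lists the authors' q-values are written as −log10, and the lists of both replicates together hold a log10 value of the same kind, also deposited as −log10, which is below 0 for most pooled regions, where the q-like value exceeds 1. Most regions of a list have the same width, and 12 of the 238 IDR peaks are narrower. The authors deposited every list on 2 genome builds, ce11 and ce10. The ce11 lists were used throughout, because the reference sequence and annotation at hand (WBcel235) are that build, and the ce10 lists entered only as an alternative for counts and replicate overlap. No coordinate was converted between builds. No column of per-sample values was left unmatched.

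Gene positions came from Ensembl release 115. RefSeq gave the names of 612 of 634 tRNA genes, with the amino acid for 607, and the names of 34 mitochondrial genes, the latter matched on strand and position. A summit is the position of highest signal in a region. A region was called promoter when its summit lay within 1000 bp of an annotated 5' end of a protein-coding transcript. Other summits were assigned to the 5' UTR, 3' UTR, coding exon, non-coding RNA exon, intron or intergenic class, in that order. The non-coding RNA exon class held exons of all genes other than protein-coding and piRNA genes, so any annotated pseudogene counted there too. A protein-coding gene was called bound when its 5' end was the nearest within 1000 bp of an IDR summit, and an RNA gene when a summit lay within 200 bp of it. These are assignments by distance, and no expression was measured. Shares of IDR peaks were compared with the shares of the pooled relaxed regions without an IDR peak. Of these 29762 regions only 1195 (4.02%) had their summit in a region of both replicates, and 16825 in a region of neither. Most of them were thus weak candidates, so these comparisons set strong regions largely against background. Tests were two-sided Fisher's exact tests, with 95% Wilson intervals for shares. Benjamini-Hochberg adjustment ran over the 7 annotation classes, 6 RNA gene classes, 16 gene lists or 7 motifs. Intervals cover counting error only. Neighbouring genes and regions are not independent, so these p-values describe positions in these 2 libraries. For gene lists the background was the 9543 protein-coding genes nearest to a summit of any pooled relaxed region. Replicate overlap was tested with 1000 circular shifts of 1 replicate's summits along each chromosome, or 100 shifts where whole regions were compared. Signal in the 2 replicates was compared across peaks by Pearson's r and Spearman's rho with 100000 permutations, where peaks are not independent replicates. Motifs were searched on both strands within 100 bp of each summit and from 500 to 700 bp to either side, and all 6-mers were scanned the same way. The number of relaxed regions in a 40000 bp window around nhr-28 and unc-119 was ranked among all tiles of that size. The plan gave no side for this rank; it was first taken as upper-tailed, and was made two-sided after the window at nhr-28 was seen to hold 0 regions, so its p-value there is not independent of the result. Odds ratios with 0 peaks on the IDR side are given as 0, a convention set after a first run in which a continuity correction had put some of them above 1.

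The gene lists, the motifs, the tests, most alternatives and the rule for the genes named were fixed before the data were examined. The rule names the genes of the 25 IDR peaks with the highest signal that have a protein-coding 5' end within 1000 bp and a region in both replicates, together with a gene on the other strand whose 5' end is also within 1000 bp, up to 4 bound members of each tested list by signal, nhr-28 and unc-119, and up to 4 RNA genes of each enriched class by signal. Because 12 of those 25 peaks were mitochondrial, further nuclear genes are named as well, and these were chosen after their values were seen. The alternatives fixed in advance were the IDR peaks with signal above the median, the strongest regions of either replicate alone (without replicate 1, without replicate 2), other distances, other overlaps, the other build and other backgrounds. Alternatives on nuclear chromosomes only, without peaks at tRNA genes, over pooled relaxed regions found in both replicates and with a background matched on GC content (5 regions per peak) were added after the data were seen, as were the motif searches in subsets of the peaks.

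Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9. The shift test, the gene list test, the 6-mer scan and the rank correlation were first tested on simulated data. The shift test called 20 of 20 sets in which 1 in 5 positions was shared and 0 of 20 random sets. The gene list test called a list with 5 bound members in 100 of 100 sets of 9500 genes and any list in 4 of 100 random sets. That list was larger than most of the lists tested here, and bound genes were drawn independently. Its results therefore do not cover small lists or neighbouring members. The 6-mer scan called a word planted in 1 in 5 of the windows together with 2 other words, which were not examined, and called 0 words in 1 set of random windows. Both sets of windows were drawn alike, so errors under the difference in GC content between summits and flanks were not tested. The rank correlation was called in 40 of 40 related and 0 of 40 independent sets.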

Results

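NHR-28, a member of the large nuclear hormone receptor family of C. elegans, was profiled by ChIP-seq through an eGFP-tagged copy in embryos of mixed stages, in 2 biological replicates. The question was where in the genome the tagged receptor was found. The authors' list of regions that passed the irreproducible discovery rate (IDR) step held 238 peaks on ce11, of which 216 lay on the 6 nuclear chromosomes and 22 on the mitochondrial chromosome. The relaxed lists from which it was drawn held 30000 regions for both replicates together, 14746 for replicate 1 and 4556 for replicate 2. Most regions had a fixed width, 324 bp in the IDR list, and the 238 peaks covered 0.0746% of the genome. The median signal of the IDR peaks was 76.4 (range 56.4 to 532) against 16.7 in the whole pooled list. A q-value of 0.05 or less was given to 349 replicate 1 regions and 236 replicate 2 regions, so that most regions of the replicate lists lay above that value. Read totals are not part of the lists used here, and the depth behind each value is therefore unknown. All 238 IDR peaks were the 238 strongest regions of the pooled list.

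The 2 replicates shared most of the strongest regions of their lists and few of the weaker ones. Of the 238 IDR peaks, 228 (95.8%, Wilson 95% interval 92.4 to 97.7) had their summit in a region of both replicates, 8 in replicate 1 only and 2 in replicate 2 only. The IDR step selects regions for agreement between these replicates, so a high share is in part built in. On the nuclear chromosomes this was 213 of 216 (98.6%), and on the mitochondrial chromosome 15 of 22. Among the 5000 strongest pooled regions below the IDR peaks the share was 22.7%. Of all 14746 replicate 1 regions, 1393 (9.45%) held a replicate 2 summit, against a mean of 1.63% and a maximum of 1.99% over 1000 circular shifts (permutation test, two-sided p = 0.002, the smallest these shifts can give). Of the 238 strongest regions of replicate 2, 92.9% held a replicate 1 summit, and this fell to 60.7% for the 1000 strongest and 43.7% for the 2000 strongest. Of the strongest regions of replicate 1, 89.1%, 49.9% and 32.9% of the same numbers held a replicate 2 summit. Across the 228 shared peaks the signal of the 2 replicates was related with r = 0.682 and rho = 0.419 (permutation p = 1e-05 for each, the smallest possible), and without the 2 peaks farthest from the median in replicate 1 the values were 0.673 and 0.412. Each peak took the strongest replicate region over its summit, so that 1 region can serve 2 peaks. The 2 peaks left out, both mitochondrial, share the replicate 1 value 248.46, and both are among the 15 mitochondrial peaks below. The 213 nuclear peaks gave r = 0.568 and rho = 0.321, and the 15 mitochondrial peaks gave r = 0.266 (p = 0.340) and rho = 0.00179 (p = 0.998). Because the IDR peaks are the strongest pooled regions, these values cover a narrowed range of signal. The 1423 pooled relaxed regions found in both replicates gave r = 0.778 and rho = 0.554, and the 1408 nuclear ones 0.762 and 0.539.

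**Figure D1:**
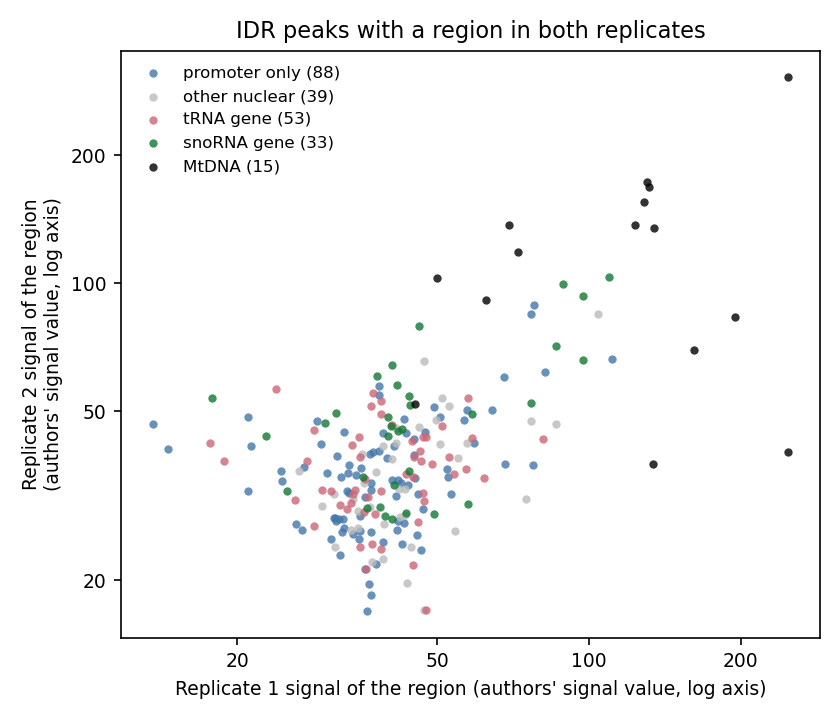
Signal of the 228 IDR peaks found in both replicates, with the authors' signal value in replicate 1 on the x axis and in replicate 2 on the y axis, both on log axes; each point is a peak, coloured by what lies near its summit. The mitochondrial peaks hold the highest values, and the nuclear classes overlap.

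The strongest nuclear peaks lay at snoRNA genes and near the 5' ends of protein-coding genes, among them rpl-3 and nhr-237. A peak at I 13475648 to 13475753 (signal 185), named after its value was seen, lay near neither these nor a tRNA gene. The strongest of all on the nuclear chromosomes, at V 12303552 to 12303702 (signal 212), covered the snoRNA gene C51F7.4 next to C51F7.3. Of the 25 strongest peaks with a protein-coding 5' end within 1000 bp and a region in both replicates, 13 were nuclear. Their signals ran from 190 for the peak 625 bp from the 5' end of sre-23, a chemoreceptor gene, beside the snoRNA gene ZK265.10, down to 107 for F36A2.7. The peak at V 1627260 to 1627583 had its summit 602 bp from the 5' end of nhr-237, itself a nuclear hormone receptor gene (signal 177). K12H4.5 followed with 169, and rpl-3, which encodes a protein of the large ribosomal subunit, with 161 at III 3867512 to 3867637. The summit at III 10759253 lay 54 bp from the 5' end of tasp-1 (146) with K01G5.10, on the other strand, 731 bp away. A peak of 128 overlapped the tRNA-Leu gene C04A11.t1 on X, 991 bp from C04A11.5. The peak at cdc-48.1, which encodes an AAA ATPase of protein quality control, had a signal of 127. Peaks with the 5' ends of 2 genes on opposite strands within 1000 bp included Y43F8C.7 and mrps-28, a mitochondrial ribosomal protein gene (123, at the snoRNA gene Y43F8C.22), Y17G9B.5 and rpl-20 (122), and ekl-4 and rps-20 (109). The MAP kinase gene mpk-2 (117, at the snoRNA gene C04G6.12) and rpl-35 (111) complete the nuclear peaks of the rule. Among weaker peaks, named after their values were seen, were the 14-3-3 gene ftt-2 (96.2), the ataxin-2 gene atx-2 (93.4) and tos-1 (100.8).

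The DNA at these summits was read from the ce11 sequence. The 41 bp centred on the rpl-3 summit, at III 3867578, are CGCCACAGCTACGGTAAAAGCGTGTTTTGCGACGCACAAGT, and those on the nhr-237 summit, at V 1627422, are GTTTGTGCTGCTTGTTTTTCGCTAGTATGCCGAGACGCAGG. Both lie in promoters as defined here. The summit at C04A11.t1, at X 13665580, lies inside the tRNA gene (X 13665555 to 13665673), in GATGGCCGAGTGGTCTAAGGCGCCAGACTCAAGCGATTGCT. Mean GC content within 100 bp of the summit was 42.5% at promoter peaks without a tRNA or snoRNA gene, 46.5% at tRNA genes, 48.6% at snoRNA genes and 23.9% on the mitochondrial chromosome.

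Promoters and non-coding RNA exons were over-represented among the peaks, and gene bodies were under-represented. A protein-coding 5' end lay within 1000 bp of 139 of 238 summits (58.4%, interval 52.1 to 64.5) against 44.9% of the 29762 relaxed regions without an IDR peak (odds ratio 1.72, 95% interval 1.33 to 2.23, two-sided Fisher's exact p = 3.45e-05). On nuclear chromosomes alone the share was 55.1% (odds ratio 1.51, exact p = 0.00308). The summits of these nuclear promoter peaks lay a median of 242 bp from the 5' end, and 98 of them (82.4%) were upstream of it. Adjusted over the 7 classes, the promoter class did not pass with the peaks above the median signal (odds ratio 1.48, exact adjusted p = 0.0594), and its adjusted p ran from 9.70e-09 to 0.0594 over the alternatives. Against the 5000 strongest relaxed regions its odds ratio was 1.34 (exact adjusted p = 0.0469). Outside promoters, 13.9% of the peaks and 2.05% of the background lay in non-coding RNA exons (odds ratio 7.71, exact adjusted p = 1.24e-16). On nuclear chromosomes the odds ratio of this class was 8.63 with 33 peaks, and without peaks at tRNA genes, an alternative added after the data were seen, it was 4.23 with 12 peaks. Coding exons held 0.840% of the peaks against 7.03% (odds ratio 0.112, exact adjusted p = 3.31e-05), introns 10.1% against 20.9% (odds ratio 0.426, adjusted p = 4.15e-05), and 3' UTRs 0 of 238 peaks (Wilson upper limit 1.59%) against 2.45% (exact adjusted p = 0.00699). The 3' UTR class lost its call in 3 alternatives, its adjusted p running from 0.00101 to 0.174. The intergenic class, 16.8% against 22.7% (odds ratio 0.689, exact adjusted p = 0.0412), did not pass on nuclear chromosomes alone (adjusted p = 0.141), and over all its alternatives the adjusted p ran from 0.0133 to 0.681.

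Genes for tRNAs, snoRNAs and other RNAs were over-represented near the peaks. A tRNA gene lay within 200 bp of 58 of 238 summits (24.4%) against 0.900% of the background (odds ratio 35.5, exact adjusted p = 1.08e-60). Of these, 53 were nuclear, and 59 of the 612 nuclear tRNA genes (9.64%, interval 7.55 to 12.2) had an IDR peak nearby. The strongest nuclear ones were C04A11.t1 (tRNA-Leu, signal 128), the pair F15G9.t1 and F15G9.t2 (tRNA-Ala, 109), ZK622.t1 (tRNA-Ala, 100.7) and sup-5 (tRNA-Trp, 100.05), the gene in which nonsense suppressor mutations are known. By amino acid the highest count of genes was tRNA-Pro, with 8 of 42, followed by tRNA-Leu with 6 of 39. Among the tRNA-Pro genes, F46G11.t1 and F46G11.t2 shared a peak, as did C16B8.t2 and C16B8.t3, while the tRNA-Leu genes had separate peaks. A snoRNA gene lay near 33 summits (13.9%) against 0.376% (odds ratio 42.6), all on autosomes, and 34 of 346 snoRNA genes had a peak. Beside C51F7.4 and C51F7.3, the strongest were ZK994.7 (192) and ZK265.10 (190). The 4 peaks near snRNA genes (odds ratio 21.2) were at sls-2.4, sls-2.1 and sls-2.2, which encode SL2 spliced leader RNAs used in trans-splicing of operon transcripts, and at R07E5.16, with signals of 78.1, 76.2, 65.04 and 65.3. With the peaks above the median signal this class did not pass (odds ratio 10.5, exact adjusted p = 0.0950, from 7.03e-05 to 0.0950 over its alternatives). The 2 peaks near miRNA genes were at cel-mir-52 (117) and cel-mir-51 (111), members of the same miRNA family. This class passed with an exact adjusted p of 0.0401 (odds ratio 6.63), which was 0.147 against the 5000 strongest relaxed regions and ran from 0.0133 to 1 over its alternatives. The rRNA class rested on 3 mitochondrial peaks alone. Other non-coding RNA genes lay near 69 summits (29.0% against 5.95%, odds ratio 6.46), of which 49 were also near a tRNA or snoRNA gene and 20 were not. With nuclear background regions matched on GC content, an alternative added after the data were seen, the odds ratio of tRNA genes went from 35.9 to 3.08 (95% interval 2.13 to 4.47) and that of snoRNA genes from 47.7 to 8.29 (4.76 to 14.4). In the same comparison that of snRNA genes went from 23.4 to 5.08, that of other non-coding RNA genes from 7.42 to 1.97, and that of miRNA genes from 7.31 to 2.01, where miRNA genes no longer passed (exact adjusted p = 0.396). Against the 5000 strongest relaxed regions the odds ratios were 10.9 for tRNA and 20.5 for snoRNA genes.

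**Figure D2:**
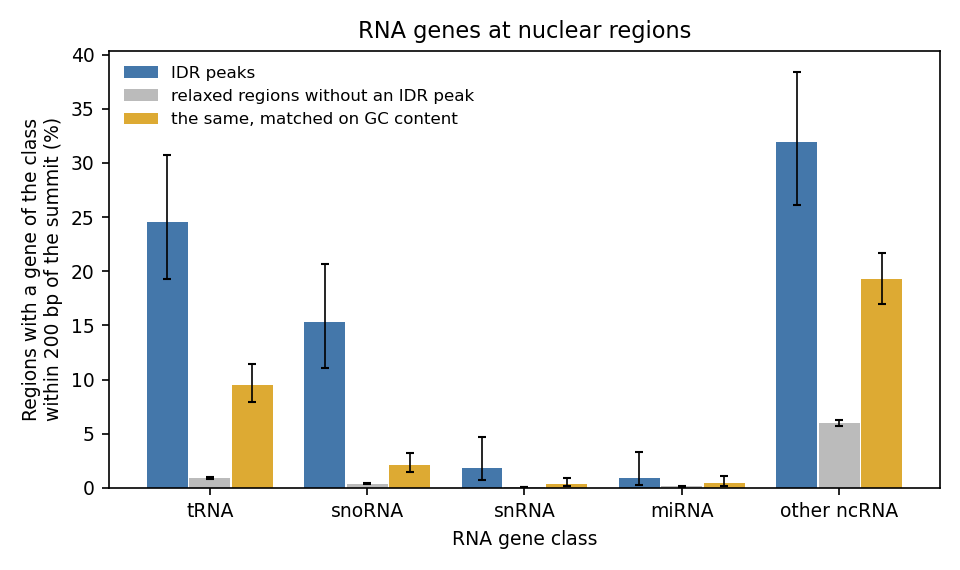
Share of nuclear regions (y axis, percent, with 95% Wilson intervals) with a gene of each RNA class (x axis) within 200 bp of the summit, for 216 IDR peaks, all relaxed regions without an IDR peak, and relaxed regions matched on GC content. The IDR share is above both backgrounds for tRNA (24.5%) and snoRNA genes (15.3%).

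Summits took different positions at the 2 kinds of gene. At tRNA genes the median summit lay 12 bp downstream of the gene's 5' end (quartiles -20 and 51 bp, 53 peaks). At snoRNA genes it lay upstream, with a median of -52 bp (quartiles -62 and -33 bp), and 28 of 33 summits (84.8%) were upstream of the gene.

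**Figure D3:**
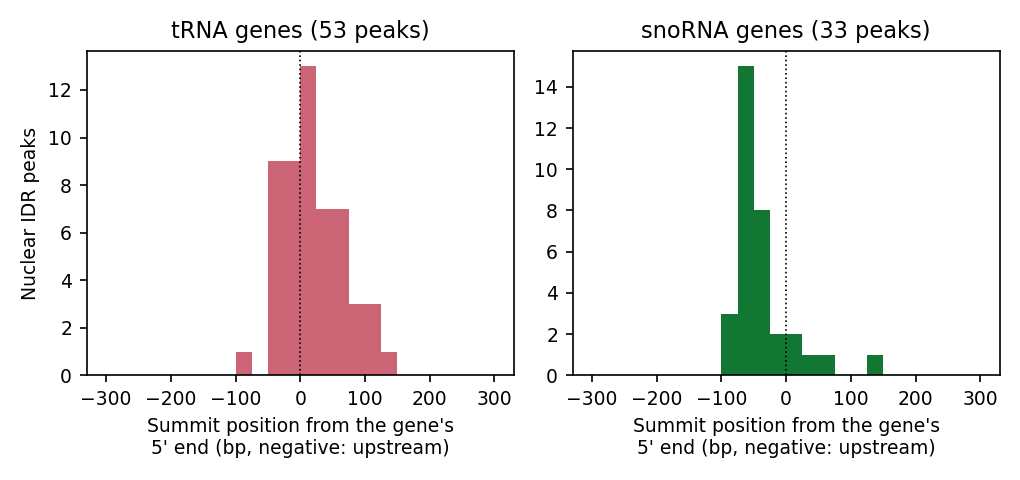
Position of the summit relative to the 5' end of the nearest tRNA gene (left, 53 peaks) or snoRNA gene (right, 33 peaks), in bp along the gene, as counts of nuclear IDR peaks on the y axis. Most snoRNA summits are at negative, upstream positions, and tRNA summits spread across the start of the gene.

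Genes of 3 of the 16 lists, those for translation factors, ribosomal proteins and nuclear hormone receptors, were over-represented among the 129 bound protein-coding genes. Translation factor genes were bound in 4 of 25 cases against 1.31% of other genes (odds ratio 14.3, 95% interval 4.84 to 42.3, Fisher's exact adjusted p = 0.00477). They were iff-2 (signal 74.8), eef-2 (73.2), whose summit lay 1 bp from the 5' end, erfa-3 (65.6) and eif-3.C (63.2), and 0 of the 25 were bound by the IDR peaks with signal above the median. Ribosomal protein genes were bound in 5 of 51 cases (odds ratio 8.21, 3.21 to 21.02, exact adjusted p = 0.00477), namely rpl-3 (161), rpl-35 (111), rpl-15 (99.7), rps-28 (78.3) and rps-1 (69.4). A further 3, rpl-20, rps-20 and rps-12, were partners on the other strand and not counted. Nuclear hormone receptor genes were bound in 7 of 150 cases (odds ratio 3.72, 1.71 to 8.11, exact adjusted p = 0.0222), led by nhr-237 (177), nhr-256 (93.9), nhr-238 (77.2) and nhr-86 (76.8), all on chromosome V, and the weakest, nhr-255, had its peak at a tRNA-Leu gene. The nuclear hormone receptor list did not pass with the strongest replicate 1 regions alone (without replicate 2, odds ratio 2.69, exact adjusted p = 0.243), and its adjusted p ran from 0.00663 to 0.243 over the alternatives. Against genes near the 5000 strongest relaxed regions 0 of the lists passed, although 3 had an unadjusted p under 0.05.

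The other 13 lists did not pass. Detoxification genes had 3 bound members of 101 (ugt-58, gst-27 and the ABC transporter gene haf-6, odds ratio 2.26, with the gst-27 peak at a snoRNA gene). Heat shock and chaperone genes had 2 of 44 (dnj-29 and dnj-13), and epidermis and cuticle genes 2 of 63, the collagen genes col-85 and col-185, both of whose peaks lay at a tRNA gene. Fatty acid metabolism had 1 of 58 (ech-1.2), homeobox genes 1 of 47 (ceh-38) and core histones 1 of 15 (his-37). The lists of intestine markers (17 genes in the background), body wall muscle (25), pharynx (9), neurons (21), germ line and maternal RNA (7), proteasome (13) and mitochondrial respiration (21) had 0 bound members. The respiration list holds nuclear genes only, so the genes of the mitochondrial chromosome that lay near IDR peaks are not among its members. The Wilson upper limits of these 7 shares ran from 13.3% for muscle to 35.4% for the germ line, so that shares up to these limits are not excluded.

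**Figure D4:**
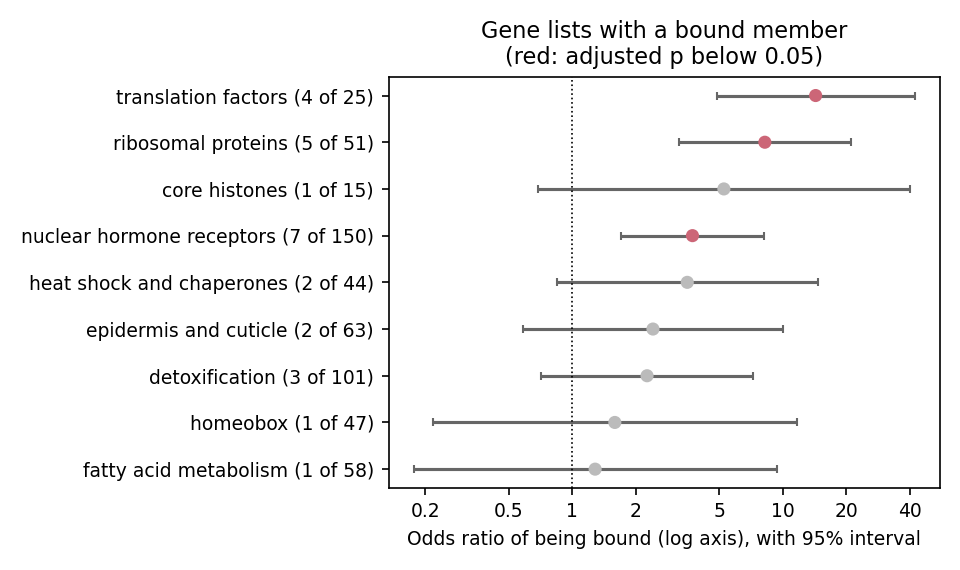
Odds ratio of being bound (x axis, log scale, with 95% interval) for each of the 9 gene lists with a bound member, with the number bound and the number in the background. Points for translation factors, ribosomal proteins and nuclear hormone receptors, in red, have an adjusted p below 0.05.

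The X chromosome held 54 of the 216 nuclear peaks (25%, interval 19.7 to 31.2) against 17.1% of the background (odds ratio 1.62, 95% interval 1.19 to 2.20, Fisher's exact p = 0.00357). It also holds 276 of the 612 nuclear tRNA genes, and 32 of its 54 peaks lay at one. Without peaks and regions at tRNA genes, X held 22 of 163 peaks (13.5%) against 16.9%, an odds ratio of 0.769 (0.490 to 1.21, exact p = 0.294), a test added after the data were seen. Per megabase, X had 3.05 peaks, chromosome III 2.61, I 2.39, II 2.09, IV 1.6 and V 1.43. On the autosomes 43.2% of the peaks and 31.0% of the background lay in the middle of the chromosome when each was divided into 3 equal parts (odds ratio 1.69, exact p = 0.00115).

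The mitochondrial chromosome, 13794 bp long, carried 24 pooled regions, of which 22 were in the IDR list. They covered 45.2% of it with a median spacing of 648 bp, and their median signal was 155 against 69.2 at promoter peaks without a tRNA or snoRNA gene. The strongest peak of the whole list, with a signal of 532, lay at 12304 to 12461 in ND5. The 12 mitochondrial peaks among the 25 named by the rule were nearest to the 5' ends of ND5, COX2 and CYTB with 2 each and ND4L, COX3, ND3, ATP6, COX1 and ND4 with 1 each.

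Sequence motifs at the summits were compared with the flanks of the same peaks. The nuclear receptor core site AGGTCA was found within 100 bp of 22 of 238 summits (9.24%, interval 6.18 to 13.6) and in 28 of 473 flank windows (5.92%), a difference that did not pass the test (odds ratio 1.62, 95% interval 0.905 to 2.90, Fisher's exact adjusted p = 0.210). The extended site AAGGTCA was at 8 summits (3.36% against 2.11%, exact adjusted p = 0.450). In subsets searched after the data were seen, AGGTCA was at 10 of 53 nuclear tRNA gene peaks against 8 of 106 flanks (odds ratio 2.85, exact adjusted p = 0.0837) and AAGGTCA at 5 of 53 against 2 of 106 (odds ratio 5.42, exact adjusted p = 0.0728). At the 130 nuclear peaks without a tRNA or snoRNA gene the odds ratios were 1.19 and 0.661. GAGAGA was more frequent at summits (31.1% against 11.6%, odds ratio 3.43, exact adjusted p = 2.26e-09) and TTTCAG less frequent (11.8% against 32.8%, odds ratio 0.274, exact adjusted p = 2.26e-09). Summits were richer in GC than flanks (42.7% against 36.2%), and against relaxed regions matched on promoter class and GC content the GAGAGA odds ratio was 0.875 (exact adjusted p = 0.572, where the 6 other alternatives, not counting subsets of peaks by nearby feature, gave 1.43e-10 to 8.65e-05) while that of TTTCAG was 0.548 (exact adjusted p = 0.0298). WGATAR, TGACTCA and CACGTG did not pass, with odds ratios of 0.740, 0.793 and 0.944. WGATAR did pass as less frequent than in flanks with the peaks above the median signal (odds ratio 0.552, exact adjusted p = 0.0433). It also passed at nuclear tRNA gene peaks (0.351, exact adjusted p = 0.0249), while against matched regions its odds ratio over all peaks was 0.952. Among the 130 nuclear peaks without a tRNA or snoRNA gene, 118 of the 6-mers were more frequent than in flanks and 55 less frequent at an adjusted p below 0.05, led by CGCAGA (39 of 130 peaks). Against matched regions 2 of these 118 also passed, CTTCGC in 24 of 130 peaks and CCGCAC in 27 of 130. Among all 6-mers tested that way, 155 (7.45%) had an unadjusted p under 0.05, where chance alone would give up to 5%.

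The loci of the transgene's genes held no IDR peak, and nhr-28 lay in a stretch of X without any relaxed region. At unc-119 (III 10902641 to 10908935) the 40000 bp window held 15 pooled relaxed regions against a median of 12 per tile (permutation rank among tiles, two-sided p = 0.555) and 0 IDR peaks. At nhr-28 (X 16354976 to 16359650) it held 0 pooled regions, 0 regions of replicate 1 and 0 of replicate 2, where the medians per tile were 12, 6 and 2. Only 10 of the 2503 tiles of the genome were also without a pooled region (permutation rank, two-sided p = 0.00879). With 80000 bp windows nhr-28 had 10 regions against a median of 24 (permutation p = 0.0560), and in replicate 2 alone 501 of the 2503 tiles held as few (permutation p = 0.401).

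**Figure D5:**
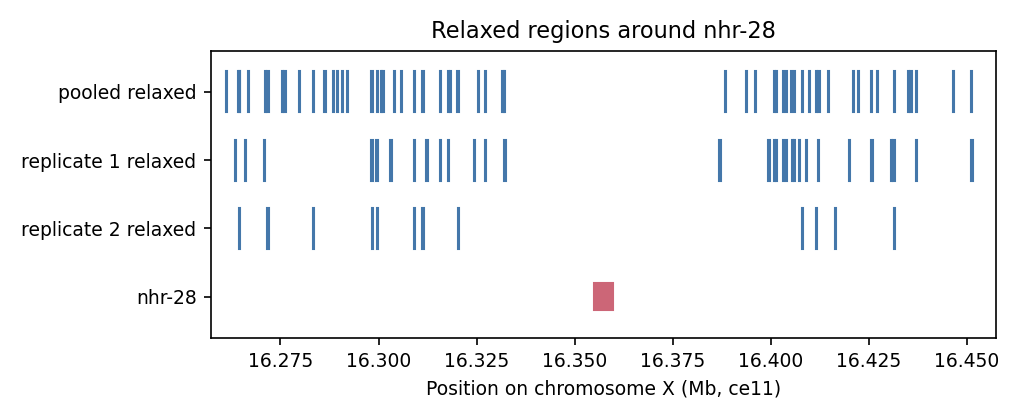
Relaxed regions (blue) of the pooled list and of each replicate within 100000 bp of nhr-28 (red) on chromosome X, with position in Mb on the x axis. The pooled list has no region between 16332364 and 16388325.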

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

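Alternatives on nuclear chromosomes only, without tRNA genes or matched on GC content, and the rank correlation over pooled relaxed regions, were chosen after the data were seen, and the rest were chosen before the data were seen. Main results and gene lists that had passed had 70 alternative values. Of these, 60 kept their direction and call, 8 no longer passed and 2 had an odds ratio on the other side of 1. These 2, X without peaks at tRNA genes and translation factors with the peaks above the median signal, did not pass on that side. Of 40 shares and counts without a test, 34 stayed within the interval or within 1.5 times and 6 moved. The 141 values of results that had not passed, most of them gene lists with few or 0 bound members, did not pass either. The odds ratios of tRNA and snoRNA genes passed in every alternative run but were as low as 3.08 and 8.29 with GC matching. The promoter share passed in every alternative run as a single test, but adjusted over the annotation classes its p ran from 9.7e-09 to 0.0594, and it lost its call with the peaks above the median signal. The share of IDR peaks found in both replicates was 98.3% with an overlap of 1 bp, 91.6% with a reciprocal overlap of 50% and 98.6% on nuclear chromosomes. With the peaks above the median signal, 3 annotation classes passed instead of 6, where fewer peaks were tested, and 0 translation factor genes were bound. Without peaks at tRNA genes the X odds ratio was 0.769, on the other side of 1. Against genes near the 5000 strongest relaxed regions 0 gene lists passed instead of 3, and the odds ratios were 3.86 for ribosomal proteins, 8.23 for translation factors and 2.91 for nuclear hormone receptors. The nuclear hormone receptor list also lost its call within 500 bp (3.37), with every gene within 1000 bp counted (2.74), and without replicate 2, where its odds ratios for single replicates ranged from 2.69 to 4.32. Against matched regions 1 motif passed instead of 2, and the GAGAGA odds ratio was 0.875. The miRNA class had 0 peaks with the summit inside a gene, and the rRNA class 0 on nuclear chromosomes. The nhr-28 window lost its low rank with 80000 bp (10 regions) and in the replicate lists ranged from 0 to 0, where replicate 2, with few regions, could not place it low. Of 93 alternative values for single classes and motifs that had passed, 76 kept their call and 14 no longer passed. The other 3 (GAGAGA, miRNA and rRNA, above) had an odds ratio on the other side of 1 and did not pass there. Of 36 for those that had not passed, 1 did. Unless stated, the cause was not tested. Read depth, unknown here, and the authors' IDR cutoff limit how many peaks could be listed.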

Other observations

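The tests of GC content, of half-sites at mitochondrial summits and of both explanations for the nhr-28 stretch were chosen after the result was seen, and the other tests of explanations were set before. The motif counts in subsets of peaks were not planned.

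Peaks with neither a promoter nor a tRNA or snoRNA gene nearby numbered 40, of which 39 were in both replicates and 15 on X. Their median signal, 73.7, was close to the 69.2 of promoter peaks. Against flanks, which were poorer in GC (35.04% against 43.7%), CACGTG lay at 4 of these 40 summits and in 0 of 80 flank windows (Fisher's exact adjusted p = 0.0260 over the motifs of this subset). It lay at 0 of 53 against 5 of 106 at tRNA genes, 3 of 33 against 3 of 66 at snoRNA genes and 3 of 90 against 12 of 180 at promoter peaks, where it did not pass. GAGAGA lay at 17 of the 40 against 8 of 80, with an exact adjusted p within each subset of 0.000560 here, 9.35e-05 at tRNA genes, 0.119 at snoRNA genes and 0.0580 at promoter peaks, and none of these 4 subsets was compared with regions matched on GC. The 7 narrow nuclear peaks, 90 to 156 bp wide, had a median signal of 185 against 73.6 for full-width ones, and 4 of them were at snoRNA genes. The bound nuclear hormone receptor genes nhr-237 and nhr-238 are neighbours, with summits at V 1627422 and V 1629497, and nhr-256 and nhr-86 lie on the same arm, with summits at V 1743603 and V 2066973, so that the members of this list are not independent.

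Peaks at tRNA and snoRNA genes make up 53 and 33 of the 216 nuclear peaks. Reads shared between identical genes were tested for tRNA genes only. A peak was near 9 of 143 tRNA genes with no identical copy (6.29%, 95% interval 3.35 to 11.5) and 50 of 469 with one. The odds ratio was 1.78 (0.851 to 3.71, Fisher's exact p = 0.145), so a contribution stays open within that interval. The test cannot decide the question for genes without a copy. It split genes on exact identity only, and a summit within 200 bp may belong to a neighbouring gene. Reads shared with nearly identical genes stay open too, and the aligner is not given. GC content does not account for all of the over-representation, since the odds ratios with matched backgrounds were 3.08 for tRNA and 8.29 for snoRNA genes. How much of the fall is due to GC cannot be told, because sequence near these summits includes the RNA genes themselves. With matching, the background share at tRNA genes rose from 0.897% to 9.54%. AGGTCA within 100 bp of the 5' end was at 10 of 59 tRNA genes with a peak and 53 of 553 without (odds ratio 1.93, 0.922 to 4.02, exact p = 0.110). These were too few to tell whether this site marks the genes with a peak. The window reaches into the gene, whose sequence identical copies share, and neighbouring genes can share a peak. The genes are thus not independent, which the interval and p-value do not allow for. AGGTCA was searched as a core site of nuclear receptors in general, and whether NHR-28 binds it is unknown here. No biological explanation beyond that site was tested, and a gain of signal at these genes that any tagged factor could show stays open, because no other factor or untagged strain was analysed here.

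The mitochondrial peaks may reflect coverage of the whole molecule more than sites. Of 27 mitochondrial replicate 1 regions, 70.4% held a replicate 2 summit against a mean of 55.6% over 10000 circular shifts (permutation p = 0.147), so positions set by noise stay possible, though few regions on a short molecule leave the test little room. AGGTCA half-sites at the mitochondrial summits, as a reason for binding, are argued against by a count of 0 among 22 peaks, since the whole chromosome holds only 2 such sites, too few for most of the peaks to have one. How the control was scaled on this chromosome was not tested, and nor was any biological explanation other than the half-sites.

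The stretch without a pooled region around nhr-28 was 55962 bp long, with 1 longer on X and 5 longer in the genome. The median such stretch on X was 2038 bp. In the shorter replicate lists it stood out less. In replicate 1 it was 54501 bp, with 7 longer on X and 29 in the genome. In replicate 2 it was 87394 bp, with 16 and 116 longer. A candidate explanation, found from these data, is that the control library came from worms that carry the nhr-28 transgene too, so that extra copies raised the background there. The unc-119 window, where a transgene copy of that gene could do the same, held 15 pooled regions against a median of 12. This count cannot decide the question, because most of the 40000 bp window lies outside the gene (III 10902641 to 10908935). Pooled regions with signals of 20.1 and 16.7 lay inside the gene. They would matter only if the transgene carries the C. elegans sequence, and the labels do not say. Removal of regions from the finished pooled list is argued against by its 30000 regions on both builds, although a removal before the list was limited to that number stays open. The strain of the control is not given in the sources used here, and no biological explanation, such as a locus with little accessible chromatin, was tested.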
